A study of Mus musculus with 6 samples.

How the data were processed

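Rat liver RNA was measured on 6 one-colour Agilent arrays, 3 from a group called model and 3 from a group called DWYG. Per the labels, both groups had part of the liver removed and were given 2-acetylaminofluorene (2-AAF), and the DWYG group also received Diwu Yanggan, a Chinese herbal capsule. The labels' texts speak of rats and the array was designed on the rat genome build rn4, while their organism field names the mouse, so the reference tables used here were those of the mouse. The label description of model replicate 3 repeats the number 2, and its replicate number was taken from its title. The labels speak of animals per group but do not state in so many words that each array came from a separate animal, so p-values measure the spread between these arrays.

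Per the file headers, the deposited scanner values are intensities from Agilent Feature Extraction 11.0.1.1 for 43553 spots, of which 42136 are not controls and belong to 24684 probes. The processed intensity is background-subtracted and spatially detrended per the file headers, and it was not normalized between arrays. Per the labels' protocols, rRNA was removed and the RNA was amplified and labelled with Cy3. The authors also deposited a value table of log2 values for 24529 probes, whose column medians lay between 5.39 and 5.40 and whose 75th percentiles were 9.00 in every column. Its scale is log2, and the scaling to 1 percentile per column was read from those values. The correspondence of its columns to the arrays is in doubt, as described with the first signed value, and whether the authors removed probes by a rule is not given in the sources used here.

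From the scanner files, the processed intensity was taken to log2, control spots and spots marked as outliers were left out, the spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. A probe counted as above background on an array when at least 50% of its usable spots were well above background per the scanner software. The test took probes above background on at least 3 of the 6 arrays, which left 17464 probes. limma 3.58.1 in R 4.3.3 fitted the group difference (lmFit and eBayes) with no block, and Benjamini-Hochberg adjusted p under 0.05 was called changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All log2 values are DWYG minus model unless stated. Where a probe was above background on no array of a group, the fold is given as a bound: the brighter group's mean was set against the mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Some signals not well above background lie above that lowest signal. A fold given as a bound is therefore approximate and no strict lower limit. Counts of probes changed at least 2-fold take measured differences and not bounds.

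The tests, the grouping and most alternatives were fixed before the data were examined. Those planned were quantile normalization, normexp background correction with an offset of 50, 2 other filters on dim probes, the authors' value table, trended and robust variances, array weights, the replicate number or the scan as a block, each array left out in turn, an equal-variance test per probe without moderated variances, and an adjusted p of 0.10. The files hold no mean spot intensity, so normexp used the median spot and median local background intensities, not spatially detrended, in place of the processed intensity. No spot was saturated, so the planned fit without saturated probes would have removed nothing and was not run. Chosen after seeing the data were scan 1 alone, the model arrays averaged into 1 sample, median scaling, the value table with its sign turned, 1 probe per transcript identifier, camera over identifier classes and weights per group.

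Gene names could not be given to the 15323 probes with an mRNA accession, since none of these accessions is in the mouse table. The gene lists fixed beforehand were therefore not tested, and the rule for named genes could not be applied to coding genes. That rule asked for the 12 highest and 12 lowest called genes, up to 4 called members of each list, the 5 highest and 5 lowest non-coding probes, and 5 liver markers. In its place, the 2 highest and 2 lowest mRNA accessions are given by identifier, the 22 tested probes with a mouse name, 3 of them listed as protein-coding, are counted and the called ones given, and ultraconserved elements keep their own names, the 5 highest and 5 lowest of those called. Of 46 probes whose identifier begins with MRNR, 37 matched a mouse RefSeq transcript once the letters MR were removed. The identifiers of the other probes, with MR left in place, gave 0 matches. That is no check on this reading, since their kinds need not occur in the mouse table. Of the 37 matched probes 22 were tested. Their names are thus those of mouse transcripts, and the rat sequence under each probe was not analysed here.

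The fit was tested on simulated arrays with the real probe means, 17446 probes and 200 changed ones, over 20 simulations. With the same spread in both groups, 60.0% of 2-fold changes and 25.5% of changes of 0.50 on the log2 scale were recovered and 6.66% of calls were false. With each group's own measured spread, which was wider in DWYG, 64.8% and 32.8% were recovered and 20.9% of calls were false, above the 5% that the threshold stands for. With no probe changed, that spread gave a mean of 0.7 false calls. A weight per group lowered the false share with 200 changed probes to 16.7%. In these runs each probe's SD over the 3 arrays of a group, itself imprecise, stood for its true spread. The excess of false calls can therefore not be put down to the wider DWYG spread alone. The share that would apply with as many changed probes as were called was not simulated.

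The number of arrays limits the precision. Between 62.3% and 75.6% of probes were above background on an array, and DWYG replicates 2 and 3, which were scanned together apart from the other 4 arrays, had the lowest shares. No label says that equal replicate numbers mark a shared animal, litter or day, and the fit with them as a block is given only with the alternatives.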

Results

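The livers of rats with partial hepatectomy and 2-AAF, a carcinogen that blocks hepatocyte division, were compared with those of rats that also received Diwu Yanggan, to see which mRNAs and long non-coding RNAs differ with the capsule. Each group had 3 arrays. The share of the 24684 probes above background was 74.2%, 69.9% and 69.8% in model replicates 1, 2 and 3, and 75.6%, 62.3% and 62.6% in DWYG replicates 1, 2 and 3. The model arrays and DWYG replicate 1 were scanned together, and DWYG replicates 2 and 3 in a second scan.

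The direction of every difference rests on the group labels of the scanner files. The authors' value table, read by its own column labels, gives the opposite sign: across 17302 matched probes its log2 differences correlated at -0.986 with those of the scanner files, and of 6279 probes called from both sources 0 had the same sign. Each of its 6 columns matched best a scanner array of the other group. Which source carries the right labels is not settled by the files, so "higher" and "lower" would exchange places throughout if the value table were right.

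**Figure D1:**
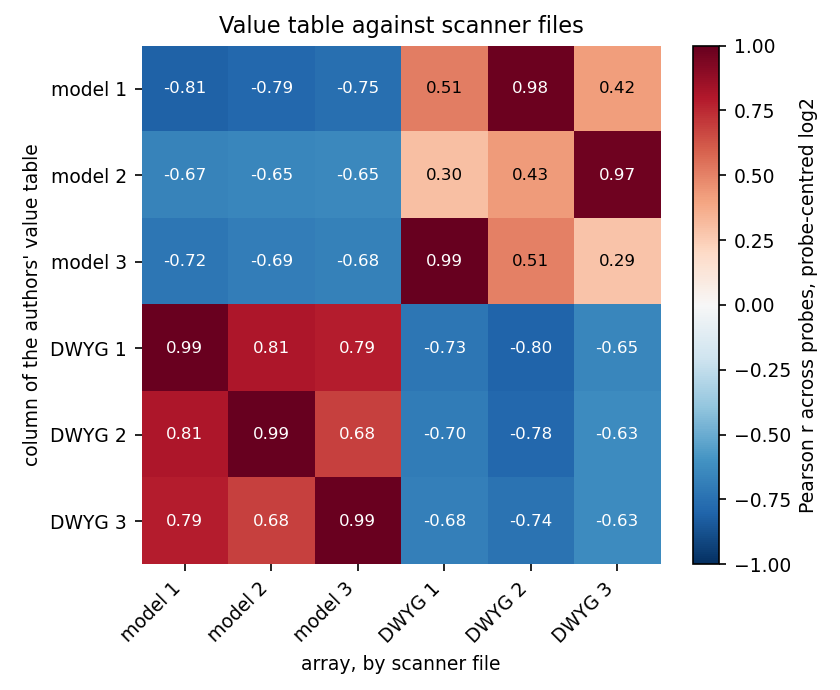
Pearson correlation across probes of each column of the authors' value table (vertical axis) with each array's scanner values (horizontal axis), after each probe was centred on its mean log2 value. The 6 best matches, from 0.975 to 0.993, all join a column to an array of the other group.

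The liver transcriptomes of the groups differed widely. Of 17464 probes tested, 3615 rose and 3219 fell in DWYG, together 39.1% (limma, Benjamini-Hochberg adjusted p under 0.05). By measured difference 1225 of these changed at least 2-fold, with 491 higher and 734 lower. These 2-fold counts include probes above background on no array of a group, whose folds are uncertain. The most changed mRNA accession, NM_053299.1, rose by a log2 difference of 10.29 ± 0.12 (SE, n = 3 per group, limma adjusted p = 9.46e-06), about 1250-fold, and was at 5.31 to 5.59 on the DWYG arrays against -5.06 to -4.73 on the model arrays. NM_001001508.1 rose by 3.21 ± 0.22 (limma adjusted p = 0.000967). NM_001037365.1 changed by -3.96 ± 0.32 (limma adjusted p = 0.0013). By the approximate bound described above, NM_053394.2 was at least 4.78-fold lower, since no DWYG array had it well above background (limma adjusted p = 0.000768). With normexp background correction NM_053299.1 was at 8.03, NM_001001508.1 at 1.58 and NM_001037365.1 at -1.78, all still called, and NM_053394.2 at 0.00 (limma adjusted p = 0.999). No table used here pairs these accessions with a gene.

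The count of calls depended on the processing and on single arrays. Without model replicate 1 it fell to 3610, with 2407 among mRNA accessions and 826 among non-coding identifiers, and without DWYG replicate 3 it was 7914. Scan 2 holds no model array, so a fit with the scan as a block and one within scan 1 alone both take their differences from DWYG replicate 1 only: they called 3649 and 7783 probes. Calls numbered 709 with normexp background correction and 1, NM_053299.1, with the 3 model arrays taken as 1 sample. Simulated arrays with the measured spread of each group gave 20.9% false calls when 200 of 17446 probes were changed. Far more probes were called here, and the false share with that many changed was not simulated, so 20.9% is no estimate for these calls.

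By an unadjusted p under 0.05 and at least 2-fold, a ranking with no control of false calls, 507 probes were higher and 785 lower. That balance turned where DWYG replicate 1 alone gave the difference (754 higher and 637 lower with the scan as a block) and with normexp (213 and 163), and it was 448 against 1314 without DWYG replicate 1. Of all probes, 8457 had an unadjusted p under 0.05, against 873 by chance.

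**Figure D2:**
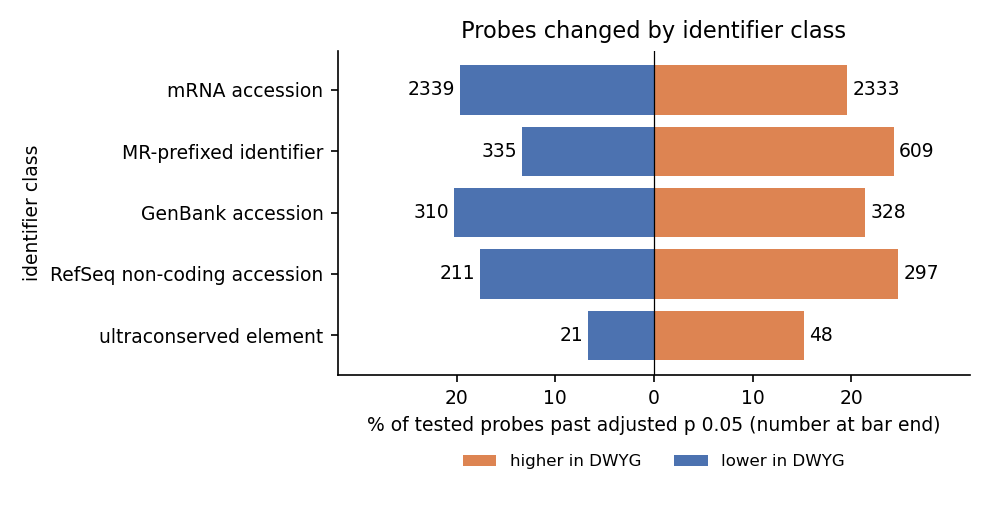
Percent of tested probes in each identifier class that rose (right) or fell (left) in DWYG at a limma adjusted p under 0.05, with their number at the bar end. MR-prefixed identifiers had 609 higher and 335 lower, while mRNA accessions had 2333 and 2339.

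Protein-coding and non-coding probes were compared on the same arrays. Of 11896 mRNA accessions tested, 2333 rose and 2339 fell, and of those at least 2-fold 244 rose and 489 fell. Among identifiers beginning with MR, the class that holds the transcripts named through the mouse table, 609 rose and 335 fell of 2508 tested, so that 64.5% of calls were higher. RefSeq non-coding accessions had 297 higher and 211 lower of 1200, and ultraconserved elements 48 and 21 of 316. GenBank accessions had 328 higher and 310 lower of 1531, and at least 2-fold 57 higher and 140 lower. The upward majorities turned without DWYG replicate 1: the MR class then had 518 higher and 646 lower, RefSeq non-coding accessions 271 and 283, ultraconserved elements 42 and 76, and GenBank accessions 287 and 462. The mRNA accessions had 2085 and 2669. No class passed camera, which compares a class with all other probes: it gave the MR-prefixed identifiers an adjusted p = 0.641 with a preset correlation and an adjusted p = 0.9 with an estimated correlation.

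Of the 22 tested transcripts with a mouse name, 4 rose, 5 fell and 13 did not pass, and the counts were the same when adjusted over the list alone. The long non-coding RNAs that rose were A930003O13Rik, by 1.58 ± 0.21 (SE, n = 3 per group, limma adjusted p = 0.00399), and Malat1, an abundant nuclear long non-coding RNA, by 0.89 ± 0.15 (limma adjusted p = 0.0071). The pseudogene transcripts Gm5088 and Npm3-ps1 rose by 0.88 and 0.44. The transcript Mx2, named for an interferon-induced GTPase and listed as a transcribed pseudogene, fell by 2.36 ± 0.09 (limma adjusted p = 0.000531), from -1.09 ± 0.12 to -3.44 ± 0.09 (SD, n = 3). Pisd-ps2 fell by 1.01, Gpr137b-ps by 0.61 and Tyms-ps, a pseudogene of thymidylate synthase, by 0.27. A transcript of the Chpt1 locus with a non-coding accession fell by 0.33. With normexp background correction only A930003O13Rik of these 9 was still called (1.35): Mx2, Malat1, Gm5088, Npm3-ps1 and Chpt1 kept their sign without passing (-1.08, 0.77, 0.82, 0.46 and -0.44), and Tyms-ps, Pisd-ps2 and Gpr137b-ps turned to 0.09, 0.35 and 0.49. Malat1, Chpt1, Gpr137b-ps and Tyms-ps lost their calls with the scan as a block, where 1 DWYG array is left and the differences moved little (0.86, -0.36, -0.61 and -0.33). Tyms-ps also lost it without any 1 model array or DWYG replicate 1 (-0.29 to -0.24), Chpt1 without model replicate 1 or 3 (-0.33 and -0.31), and Gpr137b-ps without model replicate 1 or 2 (-0.60 and -0.55). Quantile normalization ended the calls of Gpr137b-ps and Tyms-ps (-0.51 and -0.23), and median scaling those of Tyms-ps and Chpt1 (-0.21 and -0.27). Among those that did not pass, H2-K2, a class I histocompatibility pseudogene, was at 0.14 ± 0.26, Igf2os, antisense to Igf2, at 0.46 ± 0.17 and Pknox1 at 0.36 ± 0.12.

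**Figure D3:**
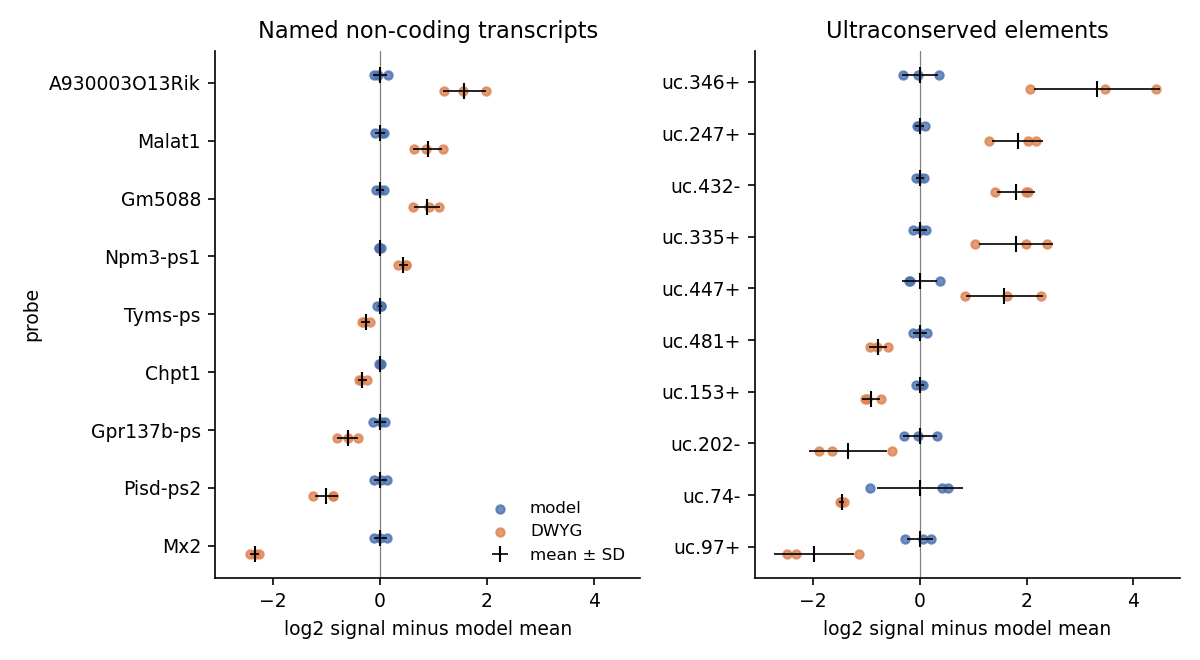
Normalized log2 signal of each array minus the model mean, for the called transcripts with a mouse name (left) and the 5 highest and 5 lowest called ultraconserved elements (right); points are arrays, crosses the mean ± SD of 3 arrays. Mx2 lay lowest of the named transcripts at -2.36 and uc.346+ highest of the elements at 3.32, and for several of the lower elements the DWYG signal was not well above background.

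Ultraconserved elements, genome stretches identical in human, mouse and rat, have a probe for each strand. Either strand of 68 of the 481 elements was called, while 233 elements had neither strand tested. Of the 316 tested probes of this class 21.8% were called, against 39.1% of all tested probes. The class is dim, with a mean log2 signal of 5.11 against 7.71 for all probes. In the dimmest 25% of all tested probes 19.7% were called. The lower share therefore does not show that these elements responded less than other transcripts. The highest was uc.346+ at 3.32 ± 0.60 (SE, n = 3 per group, limma adjusted p = 0.00937), followed by uc.247+ at 1.83, uc.432- at 1.81, uc.335+ at 1.80 and uc.447+ at 1.58. Of the lowest, uc.97+, uc.74- and uc.202- had no DWYG array well above background. By the approximate bound described above they were at least 1.83-fold, 2.22-fold and 1.26-fold lower. The other low ones, uc.153+ and uc.481+, changed by -0.91 and -0.78. With normexp background correction 3 of these 10 were still called, uc.247+, uc.432- and uc.335+. The others did not pass: uc.346+, uc.447+ and uc.481+ were at 1.62, 0.98 and -0.45, and uc.97+, uc.74-, uc.202- and uc.153+ turned to 0.48, 0.43, 0.66 and 0.45. With the scan as a block, which leaves 1 DWYG array, uc.346+, uc.335+, uc.74- and uc.202- lost their calls (3.46, 1.98, -1.49 and -0.52). Array weights ended those of uc.74- and uc.202- (-0.62 and -0.73), and quantile normalization that of uc.74- (-1.36). Leaving out 1 array ended the call of uc.74- for every array but model replicate 1 (-1.49 to -1.20). It ended that of uc.202- for every array but DWYG replicate 1 (-1.50 to -1.08), and that of uc.447+ for model replicates 1 and 3 and DWYG replicate 2 (1.49 to 1.55). For uc.97+, uc.74- and uc.202-, the values given with alternatives are measured differences and not bounds.

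Presence on the arrays was uneven. Of all probes, 14798 were above background on all 6 arrays and 5229 on none. On every model array and no DWYG array there were 122 probes, and on every DWYG array and no model array 12. These counts are not adjusted for the shares above background, which were lowest in DWYG replicates 2 and 3 (62.3% and 62.6%), the arrays of scan 2. Fewer probes could therefore pass on every DWYG array. Dim probes moved in opposite ways in the 2 scans: in the dimmest 25% of tested probes the median log2 difference from the model arrays was 0.27 for DWYG replicate 1 and -0.32 for DWYG replicates 2 and 3.

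The arrays of a group resembled each other more than those of the other group. The mean distance was 90.6 between groups and 49.1 within them, a difference of 41.6 (exact permutation p = 0.1, one-sided, the smallest that the 10 splits allow). Model arrays lay 27.3 to 38.8 apart and DWYG arrays 59.6 to 74.9. DWYG replicate 1 lay 82.0 to 85.0 from the model arrays of its own scan.

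**Figure D4:**
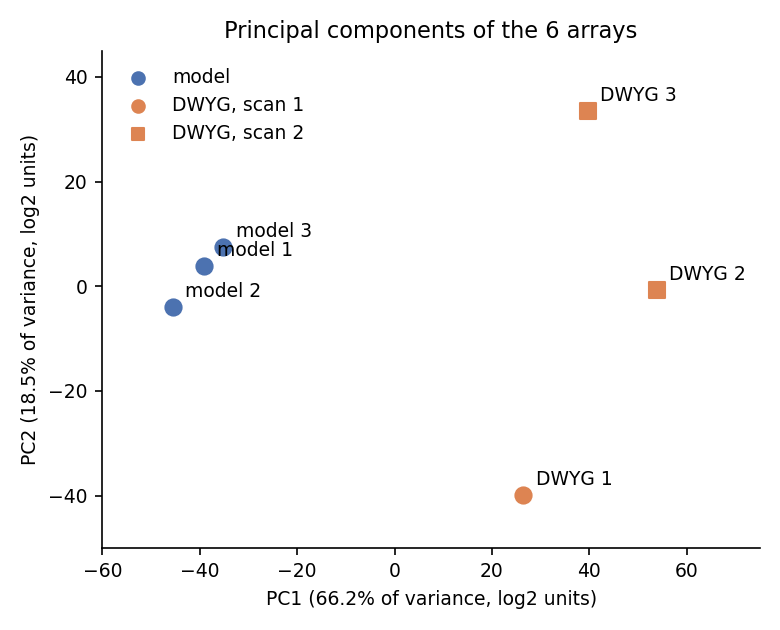
First and second principal components of the 6 arrays (log2 units) over tested probes; circles are scan 1 and squares scan 2. PC1, 66.2% of the variance, parts the groups, and PC2, 18.5%, spreads the 3 DWYG arrays from -39.9 to 33.5.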

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

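The tests in this part were chosen after the result was seen. The authors' value table, which serves only as an alternative to the scanner files, carried a signal opposed to them: its log2 differences correlated at -0.986 with theirs across probes. A mix-up of columns was weighed against one of scanner files. In all 6 columns the best-matching array was the one at that place in the list of array names sorted by character, 1 of 720 possible orders, which is consistent with a table filled in sorted order under labels in sample order. Of the 36 orders that exchange the groups whole, 1 is sorted, which argues against scanner files attached to the other group. That explanation is not excluded, since no value in the files ties an array to an animal. A biological explanation does not apply to 2 versions of the same arrays, so the direction of every group difference stays open until the authors' records are consulted.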

How the results depend on the processing

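Scan 1 alone, model arrays as 1 sample, median scaling, 1 probe per identifier, weights per group and the value table with its sign turned were chosen after seeing the data. The 6834 calls stayed within 1.5 times with quantile normalization (7521), no filter (5551), all 6 arrays above background (6972), trend (7372) and robust (6677). They also did with array weights (8550, with a weight of 30.9 for model replicate 1 from an estimate that did not converge), an unmoderated test (6252), weights per group (6461) and 1 probe per identifier (6813). Every shared call kept its sign with quantile normalization and array weights. The other settings listed leave each log2 difference as it was, so a sign could not change there. Some named calls were lost among the settings listed. Tyms-ps lost its call with quantile normalization and no filter, and Gpr137b-ps with quantile normalization. That of uc.74- was lost with quantile normalization, no filter, array weights, weights per group and the unmoderated test. That of uc.202- was lost with no filter, array weights and the unmoderated test, and that of uc.447+ with the unmoderated test. The filter on all 6 arrays left NM_053394.2, Pisd-ps2, Gpr137b-ps, uc.346+, uc.97+, uc.74-, uc.202- and uc.153+ untested. Scan 1 alone gave 7783, but its 1 DWYG array is assumed to vary like the model arrays. An adjusted p under 0.10 gave 8393. The gene lists could not be named, so their alternatives were not run, nor was the fit without saturated probes, as no spot was saturated.

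Normexp gave 709 calls, 472 among mRNA accessions and 165 among non-coding identifiers, with 376 in the 2-fold ranking, and moved the median of all probes to 0.28. It turned Tyms-ps to 0.09, Pisd-ps2 to 0.35, Gpr137b-ps to 0.49, uc.97+ to 0.48, uc.74- to 0.43, uc.202- to 0.66 and uc.153+ to 0.45. The scan block, which like scan 1 alone takes its differences from DWYG replicate 1, gave 3649, 2262 and 962 calls, with a median of 0.11, and median scaling 4363 and 2744. With the model arrays as 1 sample 1 probe, an mRNA accession, and 0 non-coding identifiers were called by limma, where 3737 probes had an unadjusted p under 0.05; fewer samples are left there, as with the scan block. For the others the cause was not tested. The replicate block gave 4523 calls and 2999 among mRNA accessions, and ended those of Tyms-ps, Gpr137b-ps, uc.74- and uc.202-. Same-numbered arrays deviated with correlations of -0.058, -0.148 and 0.087, and differently numbered ones with -0.204 to 0.237. No pairing by number was seen, but 3 arrays per group are too few to exclude it.

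Leaving out 1 array gave 3610 (without model replicate 1) to 7914 calls, and 4274 without model replicate 2; 2407 to 5367 among mRNA accessions (2874 without model replicate 2); 826 to 1836 among non-coding identifiers (971 without model replicate 2); 1135 to 1762 in the 2-fold ranking; and a separation of 31.7 to 55.7. No called named item changed sign; 6 that had not passed did. Without DWYG replicate 1 the non-coding calls turned from 954 higher and 567 lower to 831 and 1005.

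The value table as labelled reversed every shared call: 7507 calls, 5090 and 1692 by class, and 1297 in the ranking. Its values were -10.24 for NM_053299.1, -3.27 for NM_001001508.1, 3.91 for NM_001037365.1, 2.85 for NM_053394.2, -0.48 for Npm3-ps1, 0.29 for Tyms-ps, -0.97 for Gm5088, -1.60 for A930003O13Rik, 0.37 for Chpt1, 0.99 for Pisd-ps2, -0.87 for Malat1, 0.46 for Gpr137b-ps, 2.31 for Mx2, -0.37 for Pknox1, -0.56 for Igf2os, -3.41 for uc.346+, -1.85 for uc.247+, -1.88 for uc.432-, -1.82 for uc.335+, -1.70 for uc.447+, 1.49 for uc.97+, 1.34 for uc.74-, 0.97 for uc.202-, 0.81 for uc.153+ and 0.75 for uc.481+. Normexp moved the log2 difference by a median of 0.73 in the dimmest 25% of probes and -0.12 in the brightest, and calls fell from 858 to 2 and from 2051 to 217, so the loss is not one of dim probes only. The normexp run changed the intensity measure, the background method and the offset together, and their shares were not tested. Its shift of dim probes was upward, so dim falls that turned there do not decide whether those falls hold. Signal over background limits the fold to a bound for probes above background on no array of a group. The values given for such probes with an alternative are measured differences and not bounds.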

Other observations

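Apart from the counts over other splits of the arrays, the tests in this part were chosen after the results were seen. Several runs of neighbouring GenBank accessions fell together in DWYG. Of 56 runs with at least 5 tested members, 5 had a measured median at least 2-fold lower and most members called, and they held 38 probes, of which 32 fell and 0 rose. These probes are dim: 11 were above background on no DWYG array and 5 on all 3. With such probes at their approximate bound, the median of the largest run, 15 accessions with the prefix AF that all fell, was at least 3.33-fold lower. That of a run of 5 with the prefix M was at least 3.11-fold lower, and that of 1 of the 5 runs, with the prefix AJ, at least 1.90-fold. With normexp background correction 0 of the 38 were called and 8 lay below 0. That run moved dim probes upward in general, by a median of 0.73 in the dimmest 25% of tested probes. It therefore cannot decide whether the fall of these dim probes holds. The run also changed the intensity measure, and which change ended the calls was not tested. Neither their genes nor their sequences were analysed here. The hypothesis that members of a run share a change was tested over all 1531 GenBank probes: neighbours differed by a mean of 0.637 in log2 difference, against 0.82 on average over 10000 shuffles (one-sided permutation p = 1e-04, the smallest these can give). Since that test holds the runs that prompted it, it was repeated without the 7 runs whose median was at least 2-fold lower: the mean was 0.62 against 0.727 (one-sided permutation p = 1e-04). Whether neighbours are alike only because their signal levels are was not tested.

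The groups differed in 6834 probes. A shift of dim signal in the second scan is argued against as the whole cause, since 37.4% of calls in the brightest 25% of probes went in the less common direction, where a shift with signal moves like probes one way. A difference between the scans stays open, because the distance of at least 82.0 from the model arrays within scan 1, against at most 38.8 between those, rests on 1 DWYG array. The 10 splits of the arrays are too few for a share under 0.05: 1 split, the real one, gave as many calls, with 6834 against at most 0 in the others, 4672 against 0 among mRNA accessions, 1521 against 0 among non-coding identifiers, and 1292 against at most 259 in the 2-fold ranking. Every other split mixes the groups, so a clear difference between the 2 sets of arrays, whatever its cause, leaves few calls in those splits. These counts therefore do not bear on the cause. The treatment stays among the open explanations, untested.

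The DWYG arrays varied more than the model arrays, with 84.4% of the 4159 probes that have 3 spots and were above background on all 6 arrays having the larger SD in DWYG. Dim signal is argued against as the whole cause, as in the brightest 25% of probes the closest DWYG arrays differed by a median of 0.099 and the most different model arrays by 0.078. A noisier second scan stays open: its DWYG arrays lay 59.6 apart and no model arrays more than 38.8, but every pair of DWYG arrays includes an array of scan 2, which holds no model array. Model arrays made from shared RNA could not be excluded: they differed beyond spot noise in 26.7% of the probes with 3 spots, against 5% by chance and 73.6% in DWYG, and the spread of repeated labelling was not measured. Variation between animals in their response stays open, untested.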
